A study of Mus musculus with 9 samples.

How the data were processed

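The series holds 9 RNA-seq libraries of mouse bone marrow-derived macrophages, 3 each with BSA, CX3CL1 or CCL26. Per the labels' protocols, RNA was extracted with a column kit (RNeasy Mini), made into libraries with the NEBNext Ultra II RNA kit and sequenced as read pairs of 150 bp on a NovaSeq instrument. The authors deposited 1 table of counts per gene, whole numbers that were not normalized. The submitters' processing notes name STAR, featureCounts and MultiQC, without versions or order, and the builds GRCm38 and mm10; whether counting used strand is not given in the sources used here. Per the file headers, the columns end as the gene count output of STAR does. Each gene in the deposited table reached at least 0.431 CPM in 2 libraries, and the rule behind this is not given in the sources used here. Reads from overlapping or antisense genes and from near-identical copies cannot be told apart in such counts.

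Each column was matched to its library by the sample code in the labels, and groups were taken from the treatment label. No column of values was left unmatched, and no entry lacked a gene. The table gives symbols for all but 1343 of 13593 genes; 1333 of these took their name from GENCODE M21 by gene identifier and 10 had none. Coordinates are those of GENCODE M21 on GRCm38. Counts of replicates were compared by chi-square over genes of at least 20 counts: the statistic per degree of freedom was 284 and 336 between CX3CL1 replicate 1 and its replicates, and from 3.91 to 8.65 for the other 7 pairs within groups. No pair differed by less than sampling noise, so none was counted as 1 library.

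Genes were filtered with filterByExpr by group, which left 12915, and scaled by TMM factors. All 9 libraries entered 1 fit with group as the only term, and edgeR 4.0.16 (quasi-likelihood F test, R 4.3.3) tested CX3CL1 against BSA, CCL26 against BSA, CCL26 against CX3CL1 and the 3 groups together, with Benjamini-Hochberg adjustment and a threshold of 0.05. A positive log2 fold change means higher in the treatment named first. CPM values use the TMM-scaled library sizes. Depth ran from 16923982 to 23198324 counts per library.

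There were 29 gene lists with 865 members, covering chemokines and their receptors, inflammatory cytokines and NF-kB targets, interferon-stimulated genes, alternative activation, immediate-early genes, cell cycle, lipid, glycolytic, stress, lysosomal, antigen presentation, actin, mitochondrial and ribosomal genes, and markers of macrophages and of other cell types that a marrow culture can hold. The 25 lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with estimated correlations, and with fry. Fry tests whether the genes of a list move one way on balance and does not compare them with other genes.

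Groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Named genes are, per comparison, the 12 largest log2 fold changes in each direction among genes past the threshold, with a mean of at least 1 CPM and groups that do not overlap, skipping genes without a proper name. Where fewer than 10 pass, the 10 with the smallest p are named as well, with values only. The rule also takes Cx3cr1, Ccr1, Ccr2, Ccr3 and a further gene that is not reported here, and up to 4 members with the smallest p of each list as examples. Other genes are said to be chosen after their values were seen.

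Alternatives were DESeq2 size factors, upper quartile scaling, no filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, thresholds of 0.01 and 0.1, fits on the 6 libraries of each comparison, and leaving out each library. Robust dispersion and limma-voom with library quality weights were added after seeing the data. The scripts were tested on simulated counts with the means and library sizes of the real data and known changes in 200 genes per treatment. For CCL26 against BSA with all 9 libraries, edgeR recovered 0% of 67 genes changed 1.5-fold, 22.4% of 67 changed 2-fold and 81.8% of 66 changed 4-fold among 12915 genes, none in the wrong direction. Without CX3CL1 replicate 1 the shares were 50.7%, 74.6% and 87.9% among 13245 genes. Every simulated library had the spread per gene estimated in the fit, which with all 9 libraries includes CX3CL1 replicate 1. The real libraries are not equally noisy, so the shares with all 9 need not hold for the real comparisons. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).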

Results

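Messenger RNA was sequenced from mouse bone marrow-derived macrophages, which are grown from marrow precursors with the growth factors that L929 fibroblasts release into their medium (15% conditioned medium, 7 days). Marrow came from wild-type C57BL/6 animals aged 6 weeks. The macrophages received bovine serum albumin (BSA, the protein control), CX3CL1 or CCL26, each at 4 nM for 4 h. The series title names both chemokines as ligands of the receptor CX3CR1, and the comparison asks how macrophages respond to each and whether the responses differ. There were 3 libraries in each of the 3 groups. The labels do not say that replicates came from separate animals or cultures, so the p-values measure the spread between these libraries, which may be technical.

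The measurement was the number of reads per gene for 13593 genes, of which 12915 were tested. Total counts were 19461182, 19599955 and 17684435 in BSA replicates 1 to 3. They were 17783308, 16923982 and 23198324 in CX3CL1 replicates 1 to 3, and 21699679, 20084926 and 17599313 in CCL26 replicates 1 to 3. CX3CL1 replicate 1 stood apart from the others. It had 1193 genes without a count, against 80 to 170 in each of the other 8 libraries, and its scaling factor was 0.849, against 0.999 to 1.05. Its log2 values correlated with those of the other 8 libraries at a mean of 0.905 across genes, while the same mean ranged from 0.969 to 0.973 for the rest. Each leading count below is therefore given with and without this library. Expression is given in CPM, counts scaled to the size of the library, as mean ± SD over n = 3 libraries. Log2 fold changes carry a standard error (SE). It was derived as the size of the edgeR log2 fold change divided by the square root of its F statistic.

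**Figure D1:**
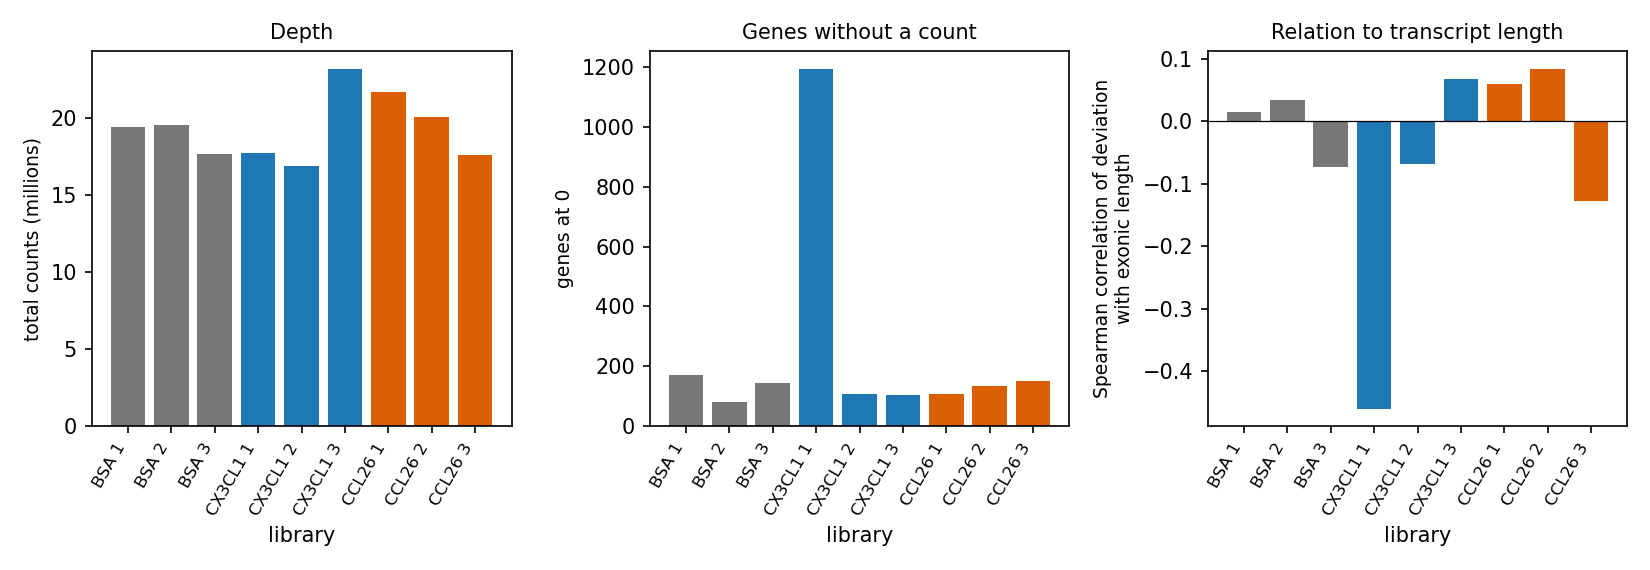
Total counts, number of genes at 0, and Spearman correlation across genes between each library's log2 deviation from the other libraries of its group (CX3CL1 replicates 2 and 3 from each other) and exonic length, with 1 bar per library (BSA grey, CX3CL1 blue, CCL26 orange). CX3CL1 replicate 1 had 1193 genes at 0 and a correlation of -0.46, while the other 8 libraries had 80 to 170 genes at 0 and correlations between -0.127 and 0.0847.

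Macrophages given CCL26 had higher levels of interferon-stimulated and inflammatory genes than those given BSA. Cxcl10, a chemokine induced by interferons that binds CXCR3, rose from 6.83 ± 0.98 to 75.7 ± 3.76 CPM, a log2 fold change of 3.47 (SE 0.229, n = 3 per group, edgeR adjusted p = 0.000713). Acod1, the enzyme that makes itaconate in activated macrophages, rose from 106 ± 11.1 to 534 ± 22.1 CPM (log2 fold change 2.33, SE 0.117, adjusted p = 0.000134, the smallest of the comparison). Rsad2, the antiviral enzyme viperin, rose from 73.0 ± 1.07 to 366 ± 10.2 CPM (2.32, SE 0.202, adjusted p = 0.00213). In the other direction, Cxcr4, the receptor of CXCL12, fell from 772 ± 13.2 to 519 ± 21 CPM (-0.57, SE 0.093, adjusted p = 0.0435).

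The remaining genes among the 12 largest increases were mostly antiviral. Ifit2 (2.49), Ifit1 (2.36) and Ifit3 (1.89) rose together with the dynamin-like GTPase Mx2 (1.84). So did the 2'-5' oligoadenylate synthetase-like gene Oasl1 (2.25) and the nucleotide kinase gene Cmpk2 (2.06), a neighbour of Rsad2. Gbp5, a guanylate-binding protein gene, rose by a log2 fold change of 2.59 from 1.64 ± 0.341 CPM (edgeR adjusted p = 0.0494), and Ifi206 rose by 2.21 (adjusted p = 0.0435). Ccrl2, an atypical receptor that binds chemerin, rose by 1.87 (adjusted p = 0.00228). The Gbp, Ifit3 and Ifi200 families hold near-identical copies between which reads can be divided, so the values of Gbp5, Ifit3 and Ifi206 are uncertain. Besides Cxcr4, the genes that fell were Dedd2 (-1.17), which encodes a protein with a death effector domain, the circadian repressor Ciart (-0.97), Nckap5l (-0.81), the zinc finger gene Zbtb2 (-0.70) and Ctdp1 (-0.66), a phosphatase of RNA polymerase II. On GRCm38 (GENCODE M21 annotation), Cxcl10 lies on chromosome 5 from 92346638 to 92348889, Acod1 on chromosome 14 from 103046977 to 103056573, Rsad2 on chromosome 12 from 26442746 to 26456452 and Cxcr4 on chromosome 1 from 128588199 to 128592293.

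In all, 50 genes were higher and 6 lower with CCL26 than with BSA (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, 12915 genes). The 3 CCL26 libraries lay on one side of the 3 BSA libraries in 33.1% of all tested genes, a pattern that chance gives in 10% of genes. Each of the 56 genes showed it too, which is no separate support, since they were picked by their difference between these libraries. Leaving out CX3CL1 replicate 1, which enters through the shared estimate of the spread, gave 1290 higher and 1227 lower of 13245, and these included all 56. The count fell when a library of the compared groups was left out and CX3CL1 replicate 1 was kept. Then 10, 11 and 9 genes were higher without BSA replicates 1, 2 and 3. Without CCL26 replicates 1, 2 and 3 the numbers were 10, 13 and 13, with none lower in these 6 fits. The 6 BSA and CCL26 libraries alone gave 1172 higher and 1245 lower. Leaving out single libraries was not tried without CX3CL1 replicate 1, so dependence on single BSA or CCL26 libraries cannot be told from the effect of its spread. Without CX3CL1 replicates 2 and 3, 35 and 45 genes were higher and 1 was lower each time. DESeq2 called 167 higher and 81 lower, among them all 56.

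**Figure D2:**
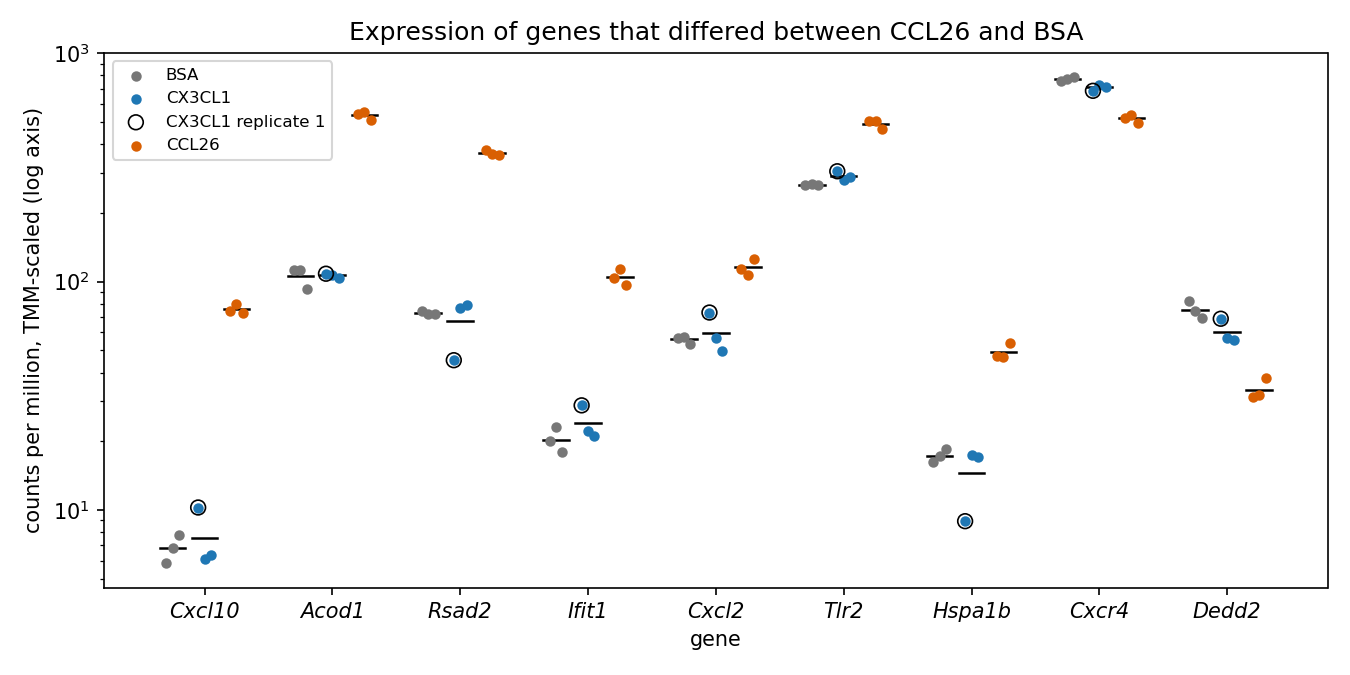
TMM-scaled CPM on a log axis for 9 genes that passed the test between CCL26 and BSA, with 1 point per library, a bar at each group mean and a circle around CX3CL1 replicate 1. For Cxcl10 the lowest CCL26 library had 72.95 CPM and the highest of the others 10.3, and the CCL26 libraries lay between 496 and 538 CPM for Cxcr4, where the lowest of the others had 685.

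Among the gene lists fixed beforehand with at least 5 tested genes, the interferon-stimulated genes had the largest median. Of 61 tested members 20 rose, none fell and 41 did not pass the test; adjusted over the list alone, 45 rose. The median log2 fold change was 0.986 (camera adjusted p = 2.19e-63, and adjusted p = 1.61e-05 with an estimated correlation). With CX3CL1 replicate 1 left out 52 of 62 rose and 1 fell. Of 51 inflammatory cytokines and NF-kB targets, 12 rose, none fell and 39 did not pass, with 21 higher and 1 lower adjusted over the list alone (median 0.402, camera adjusted p = 6.12e-22, and adjusted p = 0.00024 with an estimated correlation); with that library left out 32 rose and 2 fell. They included the glycolipid receptor gene Clec4e (1.40), the activation antigen Cd69 (1.65) and Tlr2 (0.88), a receptor for bacterial lipopeptides. Of 17 chemokine genes Cxcl10 and Cxcl2 (1.05), a neutrophil attractant, rose, none fell and 15 did not pass; adjusted over the list alone, 4 were higher and 1 lower. The values for Ccl5 (2.79, edgeR adjusted p = 0.148) and Cxcl1 (1.27, adjusted p = 0.187) did not pass. The chemokine list passed camera (0.000124), which was lost at adjusted p = 0.433 with an estimated correlation; with CX3CL1 replicate 1 left out 8 rose, 2 fell and the list passed at adjusted p = 0.0192 with an estimated correlation.

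Among 27 antigen presentation genes none passed singly and 1 was higher adjusted over the list alone (camera adjusted p = 0.0117, and adjusted p = 0.585 with an estimated correlation); Cd274, which encodes the checkpoint ligand PD-L1, had 0.83 (edgeR adjusted p = 0.139) and the peptide transporter gene Tap1 0.44 (adjusted p = 0.396). In the fit of the other 8 libraries 5 of these genes rose and 1 fell (adjusted p = 0.0674 with an estimated correlation).

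Other lists leaned downward with few or no members past the test. None of 34 glycolysis and hypoxia genes passed, nor did any adjusted over the list alone, while 30 had negative values (median -0.197, camera adjusted p = 3.49e-07, and adjusted p = 0.00777 with an estimated correlation). Examples were the mTOR inhibitor Ddit4 (-0.78, edgeR adjusted p = 0.54) and the transcription factors Bhlhe40 (-0.30, 0.603) and Mxi1 (-0.59, 0.605). Of 14 mitochondrially encoded genes 13 had negative values and none passed (median -0.239, camera adjusted p = 0.00038, and adjusted p = 0.0353 with an estimated correlation), with the ribosomal RNA genes mt-Rnr2 at -0.68 and mt-Rnr1 at -0.64. None of 44 actin, adhesion and migration genes passed (median -0.135, camera adjusted p = 0.00323, and adjusted p = 0.0389 with an estimated correlation); the small GTPase gene Cdc42 had -0.32 and the integrin gene Itgam -0.25. Neither the mitochondrial nor the actin list had a member past the test adjusted over the list alone. These counts moved with CX3CL1 replicate 1: in the fit of the other 8 libraries 19 glycolysis genes fell and none rose, 20 of 45 actin genes fell and 6 rose, and 9 mitochondrially encoded genes fell and none rose. With estimated correlations the lists then had adjusted p = 0.0212, 0.0133 and 0.128, so that the mitochondrial call was lost.

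The camera calls of 6 further lists were lost with an estimated correlation. Among 44 scavenging, Fc receptor and lysosome genes none passed, as was so adjusted over the list alone (median -0.143, camera adjusted p = 0.000629, and adjusted p = 0.0658 with an estimated correlation); Msr1, the scavenger receptor A gene, had -0.31 and the protease gene Ctsl -0.36. Of 41 immediate-early and growth-response genes Maff (1.24) and Myc (0.88), both transcription factors, rose, also adjusted over the list alone, against the list's direction (median -0.255, camera adjusted p = 0.00209, and adjusted p = 0.0956 with an estimated correlation); the other 39 did not pass, among them Egr3 at 2.96 (edgeR adjusted p = 0.31). With CX3CL1 replicate 1 left out 4 of 42 rose and 15 fell, so that most members past the test then followed the list's direction (adjusted p = 0.0777 with an estimated correlation). Of 25 oxidative stress genes none passed and 2 were lower adjusted over the list alone (median -0.133, camera adjusted p = 0.00713, and adjusted p = 0.0956 with an estimated correlation), with the heme oxygenase gene Hmox1 at -0.38 and Osgin1 at -0.56. Of 15 heat shock genes Hspa1b (1.51) and Hspa1a (1.69), near-identical copies with uncertain separate values, rose while 13 did not pass. Adjusted over the list alone 2 were higher and 2 lower; the median was -0.162 and the mean 0.0374, and camera called the list lower (0.0349, and adjusted p = 0.347 with an estimated correlation). None of 65 ribosomal protein genes (median -0.166, camera adjusted p = 0.00892) and none of 62 nuclear oxidative phosphorylation genes (median -0.139, camera adjusted p = 0.0181) passed, also adjusted over the list alone, and both calls were lost at adjusted p = 0.864 with an estimated correlation. Leaving out CX3CL1 replicate 1 moved the other lists too: 26 lysosome genes fell and 2 rose, 15 oxidative stress genes fell and 3 rose, 7 heat shock genes fell and 2 rose, 42 of 66 ribosomal protein genes fell and none rose, and 16 oxidative phosphorylation genes fell and 1 rose. With estimated correlations these lists then had adjusted p = 0.00381, 0.0158, 0.128, 0.0683 and 0.23.

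Of 13 chemokine receptor genes Ccrl2 rose and Cxcr4 fell, also adjusted over the list alone, and 11 did not pass (camera adjusted p = 0.954). The receptors described for these chemokines showed no difference beyond their spread at this depth. Cx3cr1 was at 6.55 ± 0.915 CPM with CCL26 and 6.25 ± 1.21 with BSA (log2 fold change 0.06, SE 0.208, edgeR adjusted p = 1), on chromosome 9 from 119901616 to 120069879. Ccr1 had 0.04 (SE 0.188), Ccr2 -0.31 (SE 0.878) and Ccr3 -0.20 (SE 0.859), each at an adjusted p of 1. Markers of other cell types did not move past the test: no member passed in the lists for granulocyte precursors (14 genes, median 0.292, camera adjusted p = 0.105), inflammatory monocytes (9 genes, 0.0317, 0.954), stromal cells (9 genes, 0.0427, 0.954), dendritic cells (8 genes, median -0.0553, mean 0.00223 and camera upward at 0.954) or osteoclasts (7 genes, 0.179, 0.753). Among the 16 macrophage markers none passed (median -0.0367, camera adjusted p = 0.46), with the lysozyme gene Lyz2 at -0.36 (edgeR adjusted p = 0.925). Lists with no member past the test and no camera call were cell cycle (58 genes, 0.0445, 0.954), cholesterol biosynthesis (24 genes, -0.0163, 0.954), cholesterol efflux and fatty acid synthesis (24 genes, -0.0869, 0.753), alternative activation (23 genes, -0.0367, 0.369) and the unfolded protein response (36 genes, -0.0628, 0.0815, with 1 gene lower adjusted over the list alone). With CX3CL1 replicate 1 left out, members of these 5 lists passed: 6 higher and 4 lower, 4 and 0, 2 and 7, 1 and 5, and 7 and 11. In the same fit 2 chemokine receptors rose and 1 fell, 3 granulocyte markers rose, 1 monocyte marker rose and 1 fell, and 1 macrophage marker rose and 4 fell. Of these 9 lists only the unfolded protein response had a camera call (0.0179, and adjusted p = 0.0867 with an estimated correlation). Lists of T and NK cells (2 tested genes), B cells (4), mast cells, basophils and eosinophils (3) and erythroid cells and megakaryocytes (3) were too small to test, and none of their members passed (medians 0.191, -0.0509, 1.26 and 0.195, with means of 0.0102 for B cells and -0.165 for erythroid cells). In the fit of the other 8 libraries 1 B cell marker fell and 1 marker of the mast cell list rose.

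The next comparison asks whether the ligands differ, and tests each gene between CCL26 and CX3CL1 directly. Of the 50 genes that rose with CCL26 over BSA, 42 were also called higher than with CX3CL1, among them the interferon-stimulated and inflammatory genes Cxcl10, Acod1, Rsad2 and Ifit1. Cxcl10 stood at 75.7 ± 3.76 CPM with CCL26 and 7.56 ± 2.35 with CX3CL1 (log2 fold change 3.33, SE 0.228, n = 3 per group, edgeR adjusted p = 0.000968). Acod1 stood at 534 ± 22.1 against 106 ± 2.17 CPM (2.33, SE 0.117, adjusted p = 0.000136). Nos2, the inducible nitric oxide synthase, was at 9.59 ± 0.765 against 2.19 ± 0.677 CPM (2.13, SE 0.275, adjusted p = 0.0138).

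Gbp5 (2.96), Oasl1 (2.80), Rsad2 (2.45), Ifit2 (2.39), Tgtp2 (2.38), Gbp7 (2.19), Ifit1 (2.13), Mx1 (2.08) and Cmpk2 (2.07) completed the 12 largest increases, with edgeR adjusted p-values from 0.00156 for Ifit1 to 0.0438 for Cmpk2. Tgtp2, an interferon-induced GTPase, and the Gbp genes have near-identical neighbours, and their values are uncertain. Only Ucp1, the uncoupling protein of brown fat, and Wfikkn1, a protease inhibitor gene, were lower. Ucp1 had 0.386 ± 0.0542 CPM with CCL26 and 2.82 ± 0.603 with CX3CL1 (-2.84, SE 0.402, adjusted p = 0.023). Wfikkn1 had 2.04 ± 0.558 against 6.99 ± 1.87 CPM (-1.78, SE 0.29, adjusted p = 0.0444). Ucp1 lies on chromosome 8 from 83290352 to 83298452 and Wfikkn1 on chromosome 17 from 25877628 to 25880858 (GRCm38).

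In total 51 genes were higher and 2 lower with CCL26 than with CX3CL1 (edgeR, 12915 genes). The groups did not overlap in 22.6% of all tested genes, against 10% by chance. They did not overlap in any of these 53 either, which their selection by the same difference makes nearly certain. Lists of 50 and 51 genes drawn independently would share 0.197 instead of 42, but both comparisons use the CCL26 libraries, so part of the excess may come from them. Dropping CX3CL1 replicate 1 left 724 genes higher and 614 lower, among them all 53. Leaving out BSA replicates 1, 2 and 3 gave 30, 27 and 28 higher, leaving out CX3CL1 replicates 2 and 3 gave 20 and 21, and leaving out CCL26 replicates 1, 2 and 3 gave 10, 13 and 18, with 1 gene lower without BSA replicate 1 and none in the other 7 fits. With the 6 libraries of these groups alone 4 genes were higher and none lower, and DESeq2 on all 9 called 184 and 69.

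The lists followed the genes. Of 61 interferon-stimulated genes 20 were higher, none lower and 41 not past the test, with 47 higher and 1 lower adjusted over the list alone (median 0.964, camera adjusted p = 2.41e-33, and adjusted p = 0.00011 with an estimated correlation). Of 51 inflammatory and NF-kB genes 12 were higher, none lower and 39 not past the test, with 27 higher adjusted over the list alone (median 0.647, camera adjusted p = 1.91e-17, and adjusted p = 0.000473 with an estimated correlation). With CX3CL1 replicate 1 left out 52 of 62 interferon-stimulated genes were higher and 1 lower, and 34 NF-kB genes were higher and none lower. Examples were Traf1 (1.90), a signalling adaptor, Clec4e (1.17) and Cd69 (1.51). Chemokines (Cxcl10 and Cxcl2 at 0.95, of 17), chemokine receptors (Ccrl2 at 1.63, of 13), immediate-early genes (Maff at 1.31 and Myc at 0.93, of 41) and heat shock genes (Hspa1b at 1.76, of 15) had members that rose and none that fell, without a camera call for their list (adjusted p = 0.223, 0.899, 0.218 and 0.179). Adjusted over the list alone these lists had 4, 1, 4 and 2 members higher and 0, 1, 0 and 1 lower. In the fit of the other 8 libraries 9, 2, 9 and 2 members were higher and 0, 1, 5 and 5 lower, and the chemokine list passed at adjusted p = 0.00871 with an estimated correlation.

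Ribosomal protein genes (65 tested, median -1.03) and nuclear oxidative phosphorylation genes (62 tested, median -0.785) had lower values with CCL26 than with CX3CL1, but no member passed, over all genes or adjusted over the list alone. Their camera calls (5.41e-14 and 1.95e-12) were lost at adjusted p = 0.488 with an estimated correlation for both. The medians came from CX3CL1 replicate 1: without it they were -0.0937 and -0.0973. Rpl38 shows the spread, at 281 ± 266 CPM with CX3CL1 against 98.9 ± 3.78 with CCL26. Camera also called 5 lists lower that lost the call with an estimated correlation: mitochondrially encoded genes (median -0.486, adjusted p = 0.0538 with an estimated correlation), lysosome genes (-0.24, 0.0774), glycolysis (-0.141, 0.0774), actin (-0.212, 0.0774) and the unfolded protein response (-0.104, 0.488), each with no member past the test, also adjusted over the list alone. Oxidative stress genes had 1 member lower, and antigen presentation and alternative activation genes 1 higher each, only when adjusted over the list alone. In the fit of the other 8 libraries 8 ribosomal protein, 8 oxidative phosphorylation, 12 mitochondrially encoded, 7 glycolysis and 8 oxidative stress genes were lower, with 3 higher in the last list. There too 17 lysosome genes were lower and 1 higher (adjusted p = 0.00375 with an estimated correlation), 13 actin genes lower and 3 higher (0.0153), 9 unfolded protein response genes lower and 4 higher (0.407) and 6 antigen presentation genes higher and none lower (0.0395). Of 58 cell cycle genes 8 were lower in that fit and none higher (camera adjusted p = 0.00563, and adjusted p = 0.238 with an estimated correlation). In the same fit alternative activation genes had 1 higher and 4 lower, cholesterol biosynthesis genes 4 and 1 and cholesterol efflux genes 3 and 4. Macrophage markers had 1 higher and 3 lower and granulocyte markers 1 and 0, and camera called none of these lists. The medians of the mitochondrially encoded, lysosome, glycolysis, actin and unfolded protein response lists were -0.316, -0.128, -0.124, -0.0979 and -0.00625 there. Signs differed within 2 lists without a call: granulocyte markers had a median of -0.211 and a mean of -0.173 with camera upward (0.814), and cholesterol biosynthesis genes a median of 0.0104 and a mean of -0.0225. Among the receptors, Cx3cr1 had -0.44 (SE 0.208, edgeR adjusted p = 0.423), Ccr1 -0.13, Ccr2 0.05 and Ccr3 1.11 (SE 0.893), none past the test; with CX3CL1 replicate 1 left out Ccr2 had -0.51 and Ccr3 0.56, also not past it.

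For CX3CL1 against BSA no gene passed the test with all 9 libraries. The genes with the smallest p-values included 8 with lower values, such as the circadian repressor Ciart (16.3 ± 1.27 against 24.9 ± 2.76 CPM, log2 fold change -0.62, SE 0.157, n = 3 per group) and Padi4, which converts arginine to citrulline in proteins (6.35 ± 0.358 against 9.56 ± 0.552 CPM, -0.59, SE 0.161). Others were the small GTPase gene Gem (-0.71), the transporter gene Slc35e3 (-0.69), Phf13 (-0.48), Nckap5l (-0.48) and the ubiquitin ligase gene Topors (-0.36), while Ccdc61 (0.78) and Erdr1 (1.89) had positive values. Erdr1 stood at 10.5 ± 8.66 CPM with CX3CL1 and had 0.97 with CX3CL1 replicate 1 left out. Zfp9, a zinc finger gene on chromosome 6 from 118461950 to 118479320 (GRCm38), had no count in any CX3CL1 library and 28 in the BSA libraries, at least 9.21-fold lower against a floor of 3 counts over the group. That floor covers counting error only. Each of these 10 genes had an edgeR adjusted p of 0.711.

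The count was 0 higher and 0 lower by edgeR, with 405 genes at an unadjusted p under 0.05, and DESeq2 (716 at an unadjusted p under 0.05) and limma-voom (312) also called 0. In simulated data for this comparison every library had the spread estimated in the fit, so with all 9 the noise of CX3CL1 replicate 1 entered each. There edgeR with all 9 libraries recovered 0% of the genes changed 1.5-fold, 17.9% of those changed 2-fold and 63.6% of those changed 4-fold. These shares need not hold for the real libraries, of which 1 stood apart. Simulated without CX3CL1 replicate 1, the shares were 50.7%, 70.1% and 90.9%. In the real data 3 genes were higher and 41 lower with that library left out. Genes chosen for mention after their values were seen in that fit include the stress-induced transcription factor gene Atf3 (-0.29, SE 0.0366, edgeR adjusted p = 0.000565), the AP-1 gene Junb (-0.33, SE 0.0572, adjusted p = 0.0133) and Odc1, the first enzyme of polyamine synthesis (-0.41, SE 0.0599, adjusted p = 0.00158). With all 9 libraries their adjusted p-values were 0.711, 0.716 and 0.711. Leaving out any other library left the count at 0.

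Immediate-early and growth-response genes had lower values with CX3CL1 than with BSA. Of 41 tested members 35 had negative values and none passed, over all genes or adjusted over the list alone (median -0.36, camera adjusted p = 5.46e-07, and adjusted p = 0.111 with an estimated correlation). Egr1 had -0.65, Zfp36 -0.45 and Nr4a2 -0.72. In the fit of the other 8 libraries the median was -0.229, 3 of 42 members fell and 9 were lower adjusted over the list alone. The list then passed at adjusted p = 0.0192 with an estimated correlation. For CCL26 against BSA the same fit gave a median of -0.237, with 15 members lower and 4 higher. Between CCL26 and CX3CL1 the median was -0.0367, without a camera call (adjusted p = 0.328). Both ligands share the BSA libraries, so these values cannot tell a response to CX3CL1 from a difference on the side of BSA. Ribosomal protein genes (65 tested, median 0.844, camera adjusted p = 3.6e-11) and nuclear oxidative phosphorylation genes (62 tested, median 0.673, camera adjusted p = 2.54e-10) had higher values and no member past the test, also adjusted over the list alone, and adjusted p = 0.653 with an estimated correlation for both. Both directions turned without CX3CL1 replicate 1, to medians of -0.082 and -0.0254. There 62 of 66 ribosomal protein genes had negative values, none passed, 10 were lower adjusted over the list alone, and camera called the list lower (4.64e-15, and adjusted p = 0.113 with an estimated correlation), while the oxidative phosphorylation list had no call (0.127). Rplp2 was at 576 ± 596 CPM with CX3CL1 against 238 ± 7.67 with BSA. Antigen presentation genes (27 tested, median 0.321, camera adjusted p = 0.00242), chemokines (17 tested, 0.313, 0.0452) and cell cycle genes (58 tested, 0.0733, 0.0401) had camera calls with no member past the test, also adjusted over the list alone, and adjusted p = 0.653, 0.653 and 0.565 with an estimated correlation. The antigen presentation median was -0.00137 without CX3CL1 replicate 1, with no call (0.736). In that fit the chemokine call turned downward (median -0.0634, camera adjusted p = 0.0206, and adjusted p = 0.108 with an estimated correlation), with 2 members lower, or 4 adjusted over the list alone. Cell cycle genes kept their direction, with 48 of 58 positive and 1 member higher, or 2 adjusted over the list alone (median 0.0884, camera adjusted p = 7.73e-08, and adjusted p = 0.0658 with an estimated correlation).

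Heat shock genes had a median of 0.0183 and a mean of 0.0392 with camera downward (0.837). In the fit of the other 8 libraries their median was -0.0823, 2 fell, 4 were lower adjusted over the list alone, and camera called the list lower (0.000155, and adjusted p = 0.102 with an estimated correlation). With all 9 libraries inflammatory monocyte markers had a median of -0.0268 and a mean of 0.17 with camera upward (0.689). The 61 interferon-stimulated genes had a median of 0.0869 (camera adjusted p = 0.636) and the 51 NF-kB genes -0.0972 (0.247, fry adjusted p = 0.00973), with no member past the test in either, also adjusted over the list alone. With CX3CL1 replicate 1 left out, 1 of 62 interferon-stimulated genes fell, with 1 higher and 1 lower adjusted over the list alone (median 0.0262, camera adjusted p = 0.612), and the NF-kB list was lower (median -0.0991, camera adjusted p = 8.19e-05, and adjusted p = 0.0283 with an estimated correlation) with no member past the test, and 6 lower and 1 higher adjusted over the list alone. The oxidative stress list was lower as well (median -0.0571, camera adjusted p = 1.95e-06, and adjusted p = 0.0283 with an estimated correlation), with 1 member lower, or 4 adjusted over the list alone. In the same fit 13 lists had a camera call, 2 upward and 11 downward, of which the NF-kB, oxidative stress and immediate-early lists passed with an estimated correlation. The other camera calls there were glycolysis (1 member lower, 5.39e-06, and adjusted p = 0.0688 with an estimated correlation), the unfolded protein response (2 lower, 0.000887, 0.0658), cholesterol efflux (0.045, 0.113), macrophage markers (1 lower, 0.045, 0.178) and dendritic cell markers (0.0476, 0.121), all downward, and osteoclast markers (0.0463, 0.121), upward. The alternative activation, actin and mitochondrially encoded lists had 1 member lower each and no call. Mast cell markers (3 genes, not tested) had a median of -0.0771 and a mean of 0.212. Cx3cr1 had 8.84 ± 0.949 CPM with CX3CL1 and 6.25 ± 1.21 with BSA (0.50, SE 0.208, edgeR adjusted p = 0.711), Ccr1 0.17, Ccr2 -0.36 (SE 0.88) and Ccr3 -1.30 (SE 0.894), none past the test; with CX3CL1 replicate 1 left out Ccr2 had 0.21 and Ccr3 -0.76, also not past it.

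**Figure D3:**
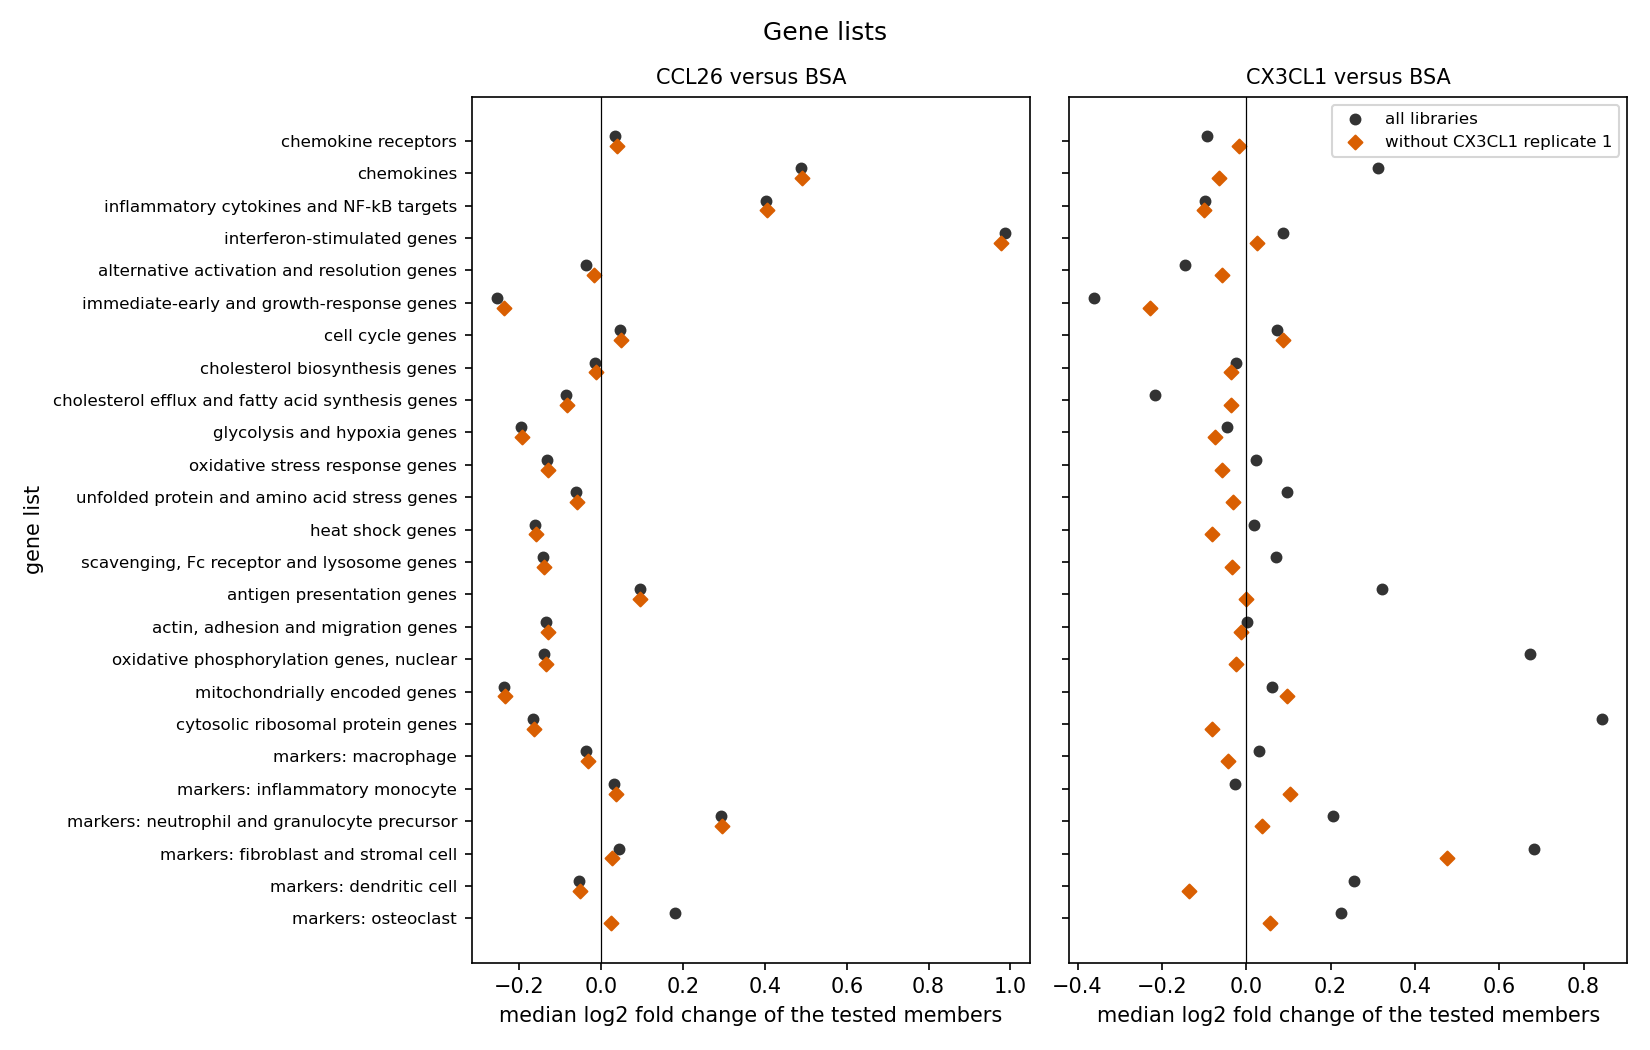
Median log2 fold change of the tested members of each gene list for CCL26 against BSA (left) and CX3CL1 against BSA (right), with all 9 libraries (circles) and without CX3CL1 replicate 1 (diamonds). For CCL26 the interferon-stimulated list lay at 0.986 and 0.977, while for CX3CL1 the ribosomal protein list went from 0.844 to -0.082.

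Tested over the 3 treatments together, 57 genes differed (edgeR, 12915 genes) and 2156 without CX3CL1 replicate 1. Without BSA replicates 1, 2 and 3 there were 22, 18 and 20, without CX3CL1 replicates 2 and 3 there were 33 and 48, and without CCL26 replicates 1, 2 and 3 there were 9, 10 and 12. DESeq2 gave 296. The log2 fold changes of the ligands against BSA correlated across genes at a Pearson r of 0.207 (Spearman 0.105); genes are not independent replicates. Without BSA replicates 1, 2 and 3 the r was 0.37, 0.41 and 0.377. It was far lower with a filter of 5 CPM in 3 libraries, as given below with the other alternatives. Both comparisons share the BSA libraries. Simulated counts for all libraries, the BSA ones included, without any effect of treatment gave a mean r of 0.503. The covariance was 0.0441 against 0.108 simulated, a difference of -0.0643. Every simulated library had the spread estimated with CX3CL1 replicate 1 in the fit, unlike the real BSA libraries. These simulated values therefore cannot serve as the expectation for all 9 libraries. With CX3CL1 replicate 1 left out the r was 0.396 (simulated 0.44) and the covariance 0.0789 against 0.0483, a difference of 0.0306. The 3 controls cannot be divided into parts of 2 libraries each, so part of any excess may come from them.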

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

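Tests of the genes at 0 at middle expression and of granulocyte RNA were chosen only after the result was seen.

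CX3CL1 replicate 1 lay far from the other 8 libraries in 4 of 5 library measures. It had 1193 genes at 0, the 10 most abundant genes took 12.6% of its counts (8.12% to 9.06% elsewhere), its TMM factor was 0.849 and its mean correlation with the other libraries was 0.905. The bound on the Dixon ratio that picked it out is reached by chance in about 1 of 20 groups; its ratios of 0.919, 0.788, 0.757 and 0.95 lay well above that bound. The 4 measures come from 1 library and are not independent.

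Its deviation from CX3CL1 replicates 2 and 3 fell with exonic length (Spearman correlation -0.46 across genes, against -0.127 to 0.0847 in the other libraries), and 140 of 1143 genes expected at 20 to 50 counts were at 0, against 0 to 7 elsewhere. Both are consistent with degraded or scarce RNA behind this library, which remains a hypothesis. The correlation with GC content was 0.204, below the 0.311 of CCL26 replicate 3, and leaves a GC bias open. A share of granulocyte RNA stays open as well, with the median of the 14 granulocyte genes at percentile 95.5 of 10000 random lists matched on expression and length. All 5 neutrophil genes named for this test stood above CX3CL1 replicates 2 and 3, by unequal amounts. S100a8 stood at 67.7 CPM against 15.7 and 15.3, S100a9 at 69.25 against 27.7 and 25.9 and Camp at 5.63 against 1.97 and 1.18. Ltf stood at 19.5 against 14.8 and 12.6, and Ngp at 15.5 against 15.3 and 12.3. Elane, which was not among the 5 and is near the floor, had 0 against 0.405 and 1.27.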

How the results depend on the processing

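Robust dispersion and library quality weights were the alternatives chosen after seeing the data. Size factors, upper quartile scaling, the absence of a filter, limma-voom and robust dispersion kept each gene and list count within 1.5 times, except that upper quartile scaling gave 1 and limma-voom 0 genes lower between CCL26 and CX3CL1 (2 as reported). The cause of each change below was not tested unless named.

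DESeq2 gave 167 higher and 81 lower for CCL26 against BSA, 184 and 69 for CCL26 against CX3CL1 and 296 over the 3 groups. Quality weights gave 2 and 27 for CX3CL1 against BSA, 1297 and 1182, 754 and 586 for the others, 2243 over the 3 groups, and 11 lists for CX3CL1 against BSA. Fits on 6 libraries gave 1172 and 1245 for CCL26 against BSA, where CX3CL1 replicate 1 no longer enters, and 4 and 0 for CCL26 against CX3CL1. At a threshold of 0.01, 15 and 0, 14 and 0 and, over the 3 groups, 20 genes passed; at 0.1, 13 and 9 genes were lower with CCL26. The correlation of the log2 fold changes of CX3CL1 versus BSA and CCL26 versus BSA was 0.00673 with a filter of 5 CPM in 3 libraries and 0.402 with quality weights. With estimated correlations 0, 5 and 2 lists passed for CX3CL1 against BSA, CCL26 against BSA and CCL26 against CX3CL1, and fry called 2 for CX3CL1 against BSA and 5 for CCL26 against BSA.

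Leaving out single libraries gave 0 to 3 genes higher and 0 to 41 lower for CX3CL1 against BSA, 9 to 1290 and 0 to 1227 for CCL26 against BSA, 10 to 724 and 0 to 614 for CCL26 against CX3CL1, 9 to 2156 over the 3 groups, 4 to 13 lists for CX3CL1 against BSA and correlations of 0.161 to 0.41. The highest gene and list counts all came without CX3CL1 replicate 1. Ccl7 had 0.19 for CX3CL1 against BSA and turned to -0.43 without CX3CL1 replicate 1 (edgeR adjusted p = 0.0247, with a range over the alternatives of 0.0247 to 0.977) and to -0.42 with quality weights; the highest value, 0.42, came without CX3CL1 replicate 3.

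The replicate numbers showed no pairing of the libraries. The 9 pairs with the same number in different groups had correlated deviations of -0.0782 to 0.0511, and the 18 with different numbers -0.066 to 0.0811. CX3CL1 replicate 1 enters the mean from which its group's deviations were taken, so pairing with that group could hardly be seen. Between BSA and CCL26 the same-number pairs had 0.0173, 0.0387 and -0.00397 and the others -0.0392 to 0.0216. With the replicate block, 14 and 0 genes passed for CCL26 against BSA, 11 and 0 for CCL26 against CX3CL1 and 16 over the 3 groups. For CCL26 against BSA all 26 named genes past the test kept their sign in each of the 19 fits, and 8 passed in each. For CCL26 against CX3CL1 all 23 kept it, and 4 passed in each. The compared groups overlapped in none of the genes past these tests. A kept sign was therefore nearly certain and is no separate support. Depth limits genes of few counts such as Zfp9.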

Other observations

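The tests of the values below were planned as 1 of the fits that leave out a library, but the genes were chosen after their values were seen. Without CX3CL1 replicate 1, modest decreases with CCL26 passed the test in many genes of the lysosome and glycolysis lists. Over all 13245 genes of that fit, 1227 were lower and 1290 higher than with BSA. Of 44 scavenging, Fc receptor and lysosome genes 26 were lower and 2 higher than with BSA (median log2 fold change -0.14, adjusted p = 0.00381 with an estimated correlation). The cathepsin genes Ctsl (-0.35), Ctsd (-0.30) and Ctsb (-0.19) and the lysosomal lipase gene Lipa (-0.25) were among them, with edgeR adjusted p-values of 3.34e-09, 2.54e-08, 4.16e-09 and 1.78e-06. Of 34 glycolysis and hypoxia genes 19 were lower and none higher (median -0.194, adjusted p = 0.0212 with an estimated correlation), such as Pkm (-0.27), Eno1 (-0.26), Pgk1 (-0.24) and Gapdh (-0.19), which encode glycolytic enzymes. With all 9 libraries none of these genes passed (edgeR adjusted p from 0.642 for Ctsl to 1 for Ctsd, Lipa, Eno1 and Gapdh).

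In the same fit, 42 of 66 ribosomal protein genes were lower with CCL26 and none higher (median -0.165, camera adjusted p = 4.37e-21, and adjusted p = 0.0683 with an estimated correlation), for example Rpsa (-0.22), Rps12 (-0.28) and Rpl7 (-0.25). Of 25 oxidative stress genes 15 were lower and 3 higher (adjusted p = 0.0158 with an estimated correlation), among them Hmox1 (-0.38) and Osgin1 (-0.56). Of 62 interferon-stimulated genes 52 were higher and 1 lower. Lyz2, the lysozyme gene of macrophages, fell from 23480 to 18340 CPM (-0.35, SE 0.0159, edgeR adjusted p = 1.78e-14). Among the markers of other cells, 3 of 14 granulocyte genes were higher and none lower, including Csf3r, the receptor of granulocyte colony-stimulating factor (0.33, adjusted p = 0.00324).

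Tests of other cell types, of a contaminant and of the BSA side in the patterns that follow were chosen only after the result was seen.

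The first pattern is the rise of interferon-stimulated and NF-kB genes with CCL26. After each library's trend over length and GC content was removed, the interferon list had a median log2 fold change of 0.966. With 1 library left out it was 0.906 to 0.97, and these values argue against such a trend as the whole cause. The median before was 0.986 by edgeR, while the values after came from limma on log2 CPM. The gap between them is therefore not the effect of the removal alone. RNA of other cells stays open: the highest median among 5 marker lists without CX3CL1 replicate 1 was 0.295, for granulocyte genes. Its bootstrap SD of 0.106 came from resampling the 14 genes of the list and does not measure the spread between libraries. S100a8 stood at 18.3 to 18.9 CPM with CCL26 against 13.8 to 16.4 with BSA. A contaminant of the CCL26 preparation such as endotoxin predicts the 12 NF-kB genes that rose as much as a response to CCL26 itself does, and the labels name no control that would separate these hypotheses. For CCL26 against BSA and against CX3CL1 1 of the 10 splits, the real one, gave 56 and 53 genes and the highest other 0, and 10 splits are too few for a share under 0.05.

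The second pattern is the set of 41 genes lower with CX3CL1 than with BSA in the fit without its replicate 1. Of these, 87.8% (36) also had lower values with CCL26, and 33 passed that test. Between CCL26 and CX3CL1 25 of the 41 differed, of which 18 were lower with CCL26 and the rest higher. Both comparisons share the BSA libraries, and simulated groups without any effect already had the same sign in 64.8% of all genes, with no such value at hand for genes picked as these were. The share therefore cannot tell a difference on the side of the BSA libraries from a response to both ligands, and both stay open as hypotheses. Among the 10 splits of the 5 libraries 1, the real one, gave 44 genes and the highest other 5, which is too few splits for a share under 0.05.

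With all 9 libraries, 10 of the 10 splits for CX3CL1 against BSA gave as many genes as the real one (0; highest other 0), which any split must when the real count is 0, so these splits say nothing about that comparison. Over the 3 groups, 2 of 100 splits drawn from 280 gave at least the real 57, with 59 in the highest other, a split that kept the CCL26 libraries together. In the fit without CX3CL1 replicate 1, 1 of 100 did, with 2156 real and 1795 in the highest other, which kept the CCL26 libraries together too. For both counts the share lay under 0.05. In the second fit, other splits that kept the CCL26 libraries together gave 1661, 1685 and 1723 genes. The share therefore reflects CCL26 against the other libraries more than a difference among all 3 treatments. The labels do not say that the libraries are separate cultures, so such splits cannot exclude chance differences between cultures.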
